A study of Mus musculus with 8 samples.

How the data were processed

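Total lung RNA of 8 FVB/N pups, 4 controls and 4 cases, was labelled with biotin and hybridised to Affymetrix arrays, 1 array per pup, per the labels' protocols. The deposited values are probe set intensities on a linear scale, 1 column per pup, for 45101 probe sets. The submitters' processing notes name the R package affy, and the summary, background correction and normalization are not given in the sources used here. Both deposited tables held the same intensities (largest difference 0). The deposited matrix also holds a column of log2 ratios, made by the authors, which equalled log2 of the intensity of case D04 over control D02 for 45101 of 45101 probe sets within 1e-06. That column sets D02 and D04 together as a pair, and the labels tie no other pups to a litter.

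Pups were grouped by the titles, and the pup number in the title names each one. Intensities were taken to log2 with no further scaling. Affymetrix control probe sets (64) were left out. In the platform annotation, 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none, and 34741 had a gene identifier found in the RefSeq gene table for GRCm38.p6, which was used for names and neighbouring genes only. Probe sets below the 40th percentile of the mean over all arrays were left out (log2 6.51). For each gene the probe set with the highest mean was kept, which gave 12856 genes. For 7 of the 39 named genes with over 1 probe set above that limit, probe sets differed in sign (Abca3, H2-D1, H2-K1, Hbb-b2, Mcm3, Nr4a2 and Spred1).

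Case and control were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The fit had no litter block, since the labels do not tie pups to litters. Fgf18 was compared by a two-sided exact permutation test. Each of 34 gene lists, fixed before the data were examined, was set against all other genes with camera at a preset correlation of 0.01, adjusted over the 34 lists. Beside it stand camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, or, as its mixed p, in either direction. The lists covered FGF signalling, other signalling, matrix, lung cell types, blood and immune cells, tissue from outside the lung, and cell states. List genes with no probe set in the annotation used here were not analysed here. Python 3 scripts prepared the tables and drew the plots with matplotlib.

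The rule for named genes, also fixed before the data were examined, took Fgf18, 8 fixed genes (Spry2, Dusp6, Etv5, Eln, Acta2, Sftpc, Scgb1a1 and Aqp5) and, in each direction, 12 genes by size among those past the threshold without overlap of the groups. Where fewer than 5 genes passed in a direction, the 12 with the smallest unadjusted p were taken instead, skipping predicted transcripts. In each list up to 4 members past the threshold were added, or, where none passed, the 2 with the smallest p. This gave 94 genes together with the 2 chosen later, Gm2102 and Dcn.

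The fit was tested on simulated data, with changed genes among 12856. Each gene was drawn independently from a normal distribution with 1 SD for both groups, the moderated SD of the real fit. The real arrays share variation between genes, with 45.09% of the residual variance in 1 component, so real recovery may be lower. With 8 arrays it recovered 76.9% of genes changed by 0.5 log2, 97.6% at 1 and 100% at 2, with 9 false calls among 195. Without the library labelled Case D52 it recovered 71.4%, 100% and 100%, with 10 false calls among 192. A simulated list shifted by 0.3 log2 was called in 20 of 20 sets, and 3 of 660 unshifted lists were called. Since the simulated genes varied independently, this does not measure false calls among correlated genes. On the real arrays, splits other than case against control called 3 to 16 of 34 lists. Those that called 15 or 16 kept cases D04, D34 and D48 together, and the others called 3 to 14.

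Array quality was read from the log2 medians (7.02 to 7.12), the correlations between arrays (0.963 to 0.995) and the difference between 3′ and 5′ probe sets of Gapdh, which ranged from -0.04 to 0.18, and of Actb, which ranged from 0.32 to 0.43. The median SD between pups over genes was 0.0977 in controls and 0.130 in cases. Alternatives changed the filter, the normalization, the choice of probe set, the moderation, the array weights, the covariates (sex, or the first principal component of the residuals), the litter block over all 24 possible pairings, the threshold and the list test, and left out each array in turn. Added after seeing the data were the 6 pairings that keep D02 with D04, list tests with an estimated correlation without the library labelled Case D52, counts and splits without that library, the 70 arrangements that leave out the lowest Fgf18, and male pups only. Deviations from the group means correlated at 0.40 between D02 and D04 across genes, which are not independent replicates, and between -0.48 and 0.35 for the other pairs.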

Results

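Lung RNA from 8 mouse pups of the FVB/N strain was measured on Affymetrix arrays, 1 array per pup. The pups belonged to a line with an inducible transgene for fibroblast growth factor 18 (FGF18). In this line the surfactant protein C promoter, active in the distal lung epithelium, drives rtTA, an activator that depends on doxycycline, and rtTA switches on an FGF18 cassette behind tet operator sites. Controls D02, D40, D50 and D58 were compared with cases D04, D34, D48 and D52, so each group held 4 pups. Per the labels, single and double transgenic pups came as pairs from 4 litters, and pups were chosen on the induction of the transgene. The titles do not tie pups to litters, and the genotype field is alike for all 8. Median log2 intensity lay between 7.02 and 7.12 on all arrays, and the number of arrays limits the precision. From Xist, the RNA of the inactive X chromosome, and Y-linked genes such as Eif2s3y, 1 control (D02) and 2 cases (D04 and D34) read as female, and the other 5 pups as male.

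The first question was whether the transgene was induced in the pups called cases. Fgf18 was far above the controls in 3 case pups and at the control level in the fourth. Its log2 intensity was 7.05, 7.76, 7.11 and 7.07 in controls D02, D40, D50 and D58 (mean 7.25 ± 0.34, SD, n = 4). It was 10.82 in D04, 12.09 in D34 and 9.82 in D48, which is 11.9, 28.7 and 5.94 times the control mean. The library labelled Case D52 read 7.66, or 1.33 times that mean and below control D40, so for this pup Fgf18 goes against the label. Over all 8 arrays the difference was 2.85 log2 (two-sided exact permutation p = 0.0571 over 70 arrangements). Without the library labelled Case D52 it was 3.66 (exact p = 0.0286, the smallest that 35 arrangements allow), but that library was left out because of its Fgf18 level, so this p is no independent test. Neither permutation test keeps pups paired by litter, since the labels do not tie pups to litters. Pups were chosen on this transgene, so its rise is no independent finding. Whether the 1 probe set for Fgf18 covers transcripts of the cassette is not given in the sources used here.

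**Figure D1:**
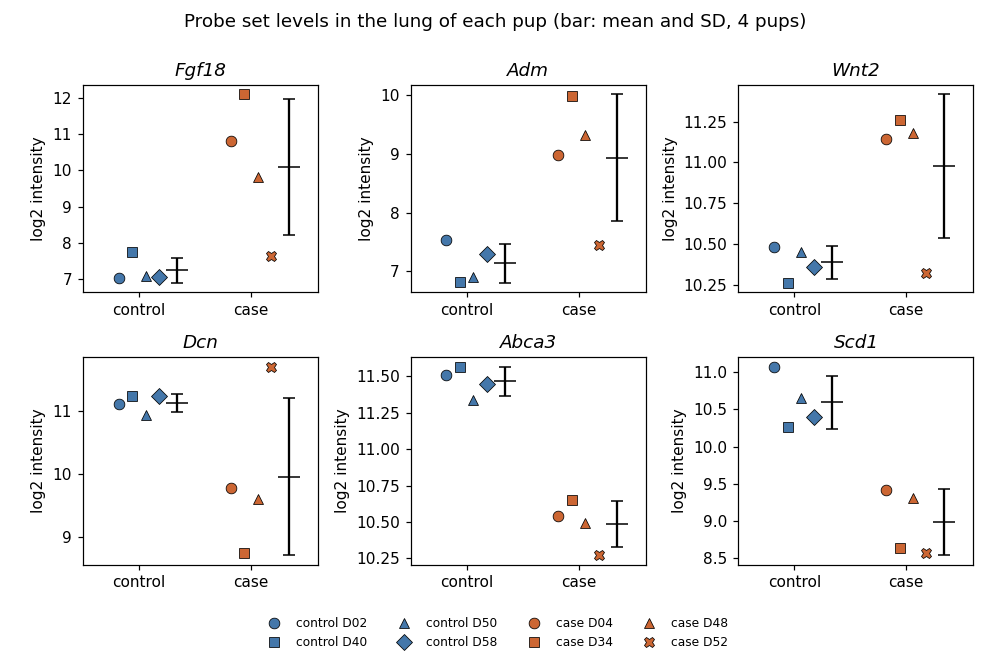
Log2 intensity (vertical axis) of 6 genes in each control and case pup, 1 symbol per pup; the bar beside each group is its mean and SD over 4 pups. Case D52, the cross, sits with the controls for Fgf18 (7.66), Adm (7.45) and Wnt2 (10.33), and with the other case pups for Abca3 (10.27) and Scd1 (8.57).

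The second question was which genes differed between case and control lungs. Abca3, the lipid transporter of the lamellar bodies in which alveolar type 2 cells store surfactant, was lower in all 4 case pups. Its log2 intensity was 11.46 ± 0.10 (SD, n = 4) in controls and 10.49 ± 0.16 in cases (SD, n = 4), a fall of 1.97-fold. Scd1, the stearoyl-CoA desaturase of fatty acid synthesis, read 10.60 ± 0.36 in controls and 8.98 ± 0.44 in cases without passing the test, and the vanin gene Vnn1 7.92 and 7.31. Of 12856 genes, Abca3 alone passed the threshold (limma, Benjamini-Hochberg adjusted p = 0.0108, log2 difference -0.98, SE 0.09, 95% interval -1.18 to -0.78). The second bright Abca3 probe set fell by 1.06 on the log2 scale, while a dim one differed by 0.06. At an unadjusted p under 0.05 there were 267 genes higher and 542 lower, against 643 expected by chance. At p under 0.01 there were 126 genes with 129 expected, and 8 of the 35 splits of the arrays gave as many. Among these are all splits that kept D04, D34 and D48 together with 1 control in place of D52 (139 to 370 genes). They are near copies of the real split. The Abca3 call was lost when control D02, D40 or D58 or case D04 or D48 was left out, with limma adjusted p from 0.0676 to 0.101. This fit ignores the pairs from litters. With a pair as a block, most of the 24 possible pairings also lost the call (limma adjusted p from 0.0160 to 0.470). Over the 6 that keep D02 with D04 it ran from 0.0276 to 0.254.

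The genes with the smallest unadjusted p below Abca3 missed the threshold and are given as values. Among the lower ones, log2 differences were -1.61 for Scd1 (limma adjusted p = 0.161), -0.61 for Vnn1 (adjusted p = 0.161), -0.33 for Paqr6, -0.42 for Abi3bp, -0.32 for Gas6, -0.28 for Cd209f, -0.38 for Tnn, -0.24 for Slc2a12, -0.36 for the long noncoding RNA Neat1, -0.60 for Rimklb and -0.52 for the aldehyde oxidase Aox3. Among the higher ones, they were 0.48 for Eci1 (adjusted p = 0.377), a mitochondrial enzyme of fatty acid oxidation, and 0.56 for Lrg1 (adjusted p = 0.377). They were 0.76 for the glutathione transferase Gstm5, 1.05 for the chitinase-like macrophage gene Chil3, 1.80 for the peptide hormone adrenomedullin (Adm), 1.0 for Hsd11b1, which regenerates active glucocorticoid, and 0.54 for the metalloprotease Adam12. They were 0.26 for Trub1, 0.26 for Pus7l, 0.42 for the ceramide synthase Cers6 and 0.26 for Map2k1, the kinase MEK1. From Paqr6 onward the adjusted p of each was 0.736. The groups did not overlap in 509 genes (3.96%), where chance gives 2.86%.

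With the library labelled Case D52 left out, a choice singled out after its Fgf18 level was seen, 6 genes passed the threshold. Fgf18 was higher by 3.66 log2 (limma adjusted p = 0.0449), Adm by 2.30 (adjusted p = 0.0247), Wnt2, a signal of the lung mesenchyme, by 0.80 (adjusted p = 0.0162) and the predicted gene Gm2102 by 1.43 (adjusted p = 0.0449). Decorin (Dcn), a collagen-binding proteoglycan, fell by 1.74 (adjusted p = 0.0449) and Abca3 by 0.90 (adjusted p = 0.0152). Each change held in 3 of 3 case pups. In the left-out library Adm read 7.45, Wnt2 10.33 and Gm2102 6.79, all within the range of the controls, and Dcn 11.69, above each control. At p under 0.05 there were 1632 genes, with 643 expected by chance, and at p under 0.01 there were 537, with 129 expected. Gm2102 and Dcn fall outside the naming rule and were chosen after their values were seen.

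Gene groups fixed beforehand were then compared with all other genes. In case pups D04, D34 and D48, the medians of genes of club and ciliated cells, smooth, heart and skeletal muscle, collagens and elastic fibres lay below the control mean, and that of targets and feedback regulators of FGF and ERK signalling above it. In the library labelled Case D52 these medians ran from -0.08 to -0.02, except 0.28 for heart and skeletal muscle genes. With camera at a preset correlation, 15 of 34 lists passed the threshold, 1 higher and 14 lower, and none of the 15 passed with an estimated correlation (smallest adjusted p = 0.412 with an estimated correlation) or by fry (smallest adjusted p = 0.276). Without the library labelled Case D52, 16 lists passed, 13 of them shared, and again none did with an estimated correlation (smallest adjusted p = 0.286 with an estimated correlation) or by fry (smallest adjusted p = 0.0850). Of the 35 splits of the arrays into 4 and 4, 5 gave at least 15 lists. Those 5 are the real split and the near copies of it that set 1 control in place of D52. Over all 34 lists the one member past the threshold over all genes was Abca3. A shift is the list's median log2 difference from the control mean.

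Most genes of the club cell list mark the secretory cells of the small airways, but it also holds Kdr of the vascular list and Chad of the cartilage list. It had a median difference of -0.45 log2, with 19 of 20 members below 0 and 20 not passing over all genes. The shift was -0.26 in D04, -0.85 in D34 and -0.48 in D48 and -0.06 in the library labelled Case D52. The call (camera adjusted p = 7.99e-09) was lost with an estimated correlation (adjusted p = 0.412 with an estimated correlation). Adjusted over the list alone, 1 member (Aox3, -0.52) passed, and 15 passed without the library labelled Case D52. Cyp2f2, a cytochrome P450 of club cells, differed by -0.56, and Scgb1a1, the club cell secretory protein, by -0.29 (limma adjusted p = 0.736 for both). Scgb3a1, a secretoglobin of airway secretory cells named after its values were seen, differed by -2.47 and read 7.42 in control D40, within the range of 6.30 to 8.04 in cases D04, D34 and D48. Ciliated cell genes had a median of -0.32, with 21 of 22 below 0 and 22 not passing over all genes (camera adjusted p = 2.44e-09, and adjusted p = 0.412 with an estimated correlation). Adjusted over the list alone, 2 members passed, the axonemal genes Tekt1 (-0.32) and Dnaic2 (-0.57), and 14 passed without the library labelled Case D52. The shift was -0.67 in D34 and -0.05 in the library labelled Case D52. The 3′ minus 5′ difference of Actb, a sign of RNA quality, was 0.43, 0.38 and 0.39 log2 in D04, D34 and D48, 0.32 in the library labelled Case D52, 0.40 in control D40 and 0.36 to 0.37 in the other controls. That of Gapdh was 0.15, -0.04 and 0.01 in D04, D34 and D48, -0.02 in the library labelled Case D52, 0.18 in control D40 and 0.01 to 0.04 in the other controls.

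FGF and ERK targets and feedback regulators had a median of 0.06, with 17 of 26 above 0, 26 not passing over all genes and 0 adjusted over the list alone (camera adjusted p = 0.0235, and adjusted p = 0.412 with an estimated correlation). The list's shift was 0.11 in D04, 0.10 in D34, 0.15 in D48 and -0.05 in the library labelled Case D52. Log2 differences were 0.70 for Myc, 0.38 for the ERK phosphatase Dusp6, 0.29 for Spred1, 0.24 for the transcription factor Etv5 and 0.08 for Spry2. Without the library labelled Case D52, Myc (0.88), Dusp6 (0.52), Spry4 (0.65) and Dusp4 (0.60) passed adjusted over the list alone, and Spry2 (0.17) and Etv5 (0.41) did not. FGF ligands and receptors had a median of -0.02 with 12 of 12 members not passing, 0 adjusted over the list alone (camera adjusted p = 0.626, and adjusted p = 0.691 with an estimated correlation), with -0.16 for Gpc3 and -0.16 for Fgfr3.

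Several groups of stromal and matrix genes lay lower. Collagens had a median of -0.16, with 21 of 25 members below 0, 0 passing over all genes and 0 adjusted over the list alone (camera adjusted p = 0.000171, and adjusted p = 0.412 with an estimated correlation). Col1a1 differed by -0.54 and Col16a1 by -0.33, and 8 members passed over the list alone without the library labelled Case D52. Elastic fibre genes had a median of -0.21, with 13 of 18 below 0 and 0 passing over all genes or adjusted over the list alone (camera adjusted p = 0.0235, and adjusted p = 0.412 with an estimated correlation). Elastin (Eln) differed by -0.35 and fibrillin 2 (Fbn2) by -0.38, whereas Fbln1 differed by 0.29. Smooth muscle and myofibroblast genes had a median of -0.28, with 16 of 21 below 0 and 0 passing over all genes or adjusted over the list alone (camera adjusted p = 0.00207, and adjusted p = 0.412 with an estimated correlation). Smooth muscle actin (Acta2) differed by -0.31, Actg2 by -0.52 and Aspn by -0.42. Growth factor genes of the IGF, TGF-beta, PDGF and VEGF families had a median of -0.20, with 22 of 27 below 0 and 0 passing over all genes or adjusted over the list alone (camera adjusted p = 0.000171, and adjusted p = 0.412 with an estimated correlation). Tgfb3 differed by -0.34 and Inhba by -0.27. Without the library labelled Case D52, 9 elastic fibre, 8 smooth muscle and 8 growth factor genes passed adjusted over their list alone. Over these 4 lists the shift was -0.32 to -0.14 in D04, -0.64 to -0.27 in D34, -0.17 to -0.08 in D48, -0.08 to -0.02 in the library labelled Case D52 and -0.06 to 0.11 in controls.

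Heart and skeletal muscle genes, markers of tissue outside the lung parenchyma, had a median of -0.53, with 13 of 15 below 0 and 0 passing over all genes or adjusted over the list alone (camera adjusted p = 0.000165, and adjusted p = 0.434 with an estimated correlation). The shift was -0.65 in D04, -1.52 in D34, -0.41 in D48 and 0.28 in the library labelled Case D52, and it ranged from -0.20 to 0.33 in controls. Without that library the median was -0.83 and 13 of 15 members passed over the list alone. Acta1 differed by -0.50 and Atp2a1 by -0.25. Lymphatic endothelium and mesothelium genes had a median of -0.30, with 12 of 12 below 0 and 0 passing over all genes or adjusted over the list alone (camera adjusted p = 0.000111, and adjusted p = 0.412 with an estimated correlation). The shift was -0.29 in D04, -0.77 in D34, -0.27 in D48 and -0.02 in the library labelled Case D52, and it ranged from -0.25 to 0.24 in controls. Without that library 5 members passed over the list alone. Rspo1 differed by -0.78 and Reln by -0.28.

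**Figure D2:**
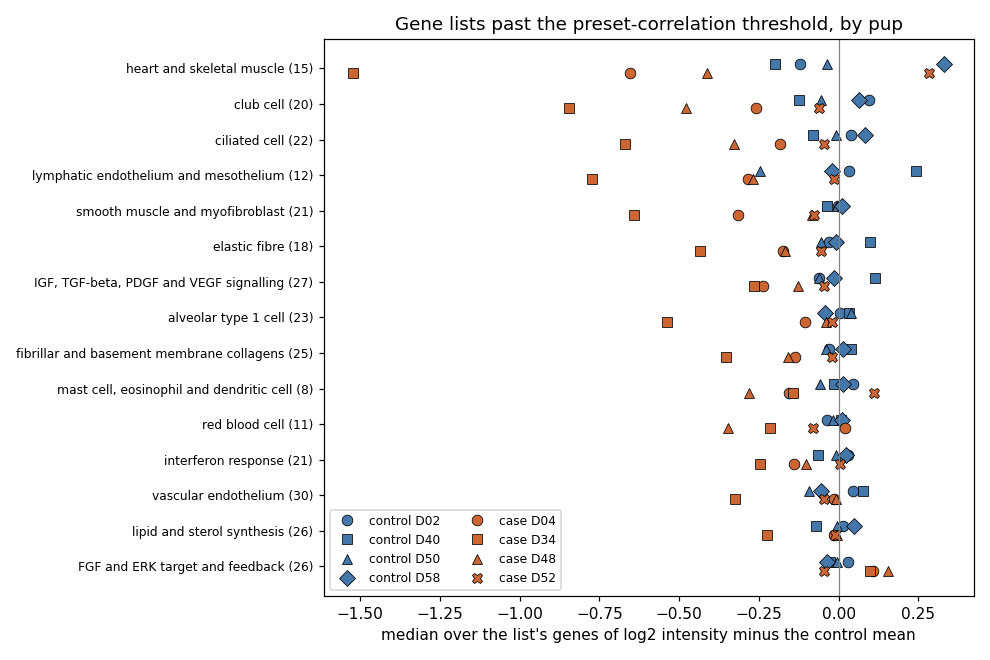
Median over each list's genes of log2 intensity minus the control mean (horizontal axis) for the 15 lists past the preset-correlation threshold, with the number of genes in brackets and 1 symbol per pup. Case D34, the orange square, lies at -0.85 for club cell genes and -1.52 for heart and skeletal muscle genes, and case D52, the cross, at -0.06 and 0.28.

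Alveolar type 1 genes had a median of -0.19, with 22 of 23 below 0 and 0 passing over all genes or adjusted over the list alone (camera adjusted p = 0.000204, and adjusted p = 0.551 with an estimated correlation). The shift was -0.54 in D34 and from -0.11 to -0.02 in the other 3 case pups. The aquaporin gene Aqp5 differed by -0.29, Akap5 by -0.22 and Sema3a by 0.38. Alveolar type 2 genes had a median of -0.06 and did not pass in one direction (camera adjusted p = 0.10, and adjusted p = 0.691 with an estimated correlation). Their shift was 0.05 in D04, 0.04 in D34, -0.10 in D48 and -0.17 in the library labelled Case D52, and -0.03 to 0.10 in controls. Of 25 members 1 was lower over all genes (Abca3) and 24 did not pass, and Abca3 and Scd1 passed adjusted over the list alone. By fry this was the 1 list with members changed in either direction (mixed adjusted p = 0.000986). The surfactant gene Sftpc differed by 0.03, against an SD between control pups of 0.07. Its mean of log2 14.58 lay near the brightest probe sets of the arrays, where a difference may not show in full. Its flat value therefore does not tell whether Sftpc changed. Vascular endothelium genes had a median of -0.10, with 26 of 30 below 0 and 0 passing over all genes or adjusted over the list alone (camera adjusted p = 0.00570, and adjusted p = 0.551 with an estimated correlation), with -0.17 for Calcrl. The vascular shift was -0.33 in D34 and -0.01, -0.01 and -0.05 in D04, D48 and the library labelled Case D52, within the control range of -0.09 to 0.08.

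Of the remaining lists, 4 passed at the preset correlation, all lower, with no member past the threshold over all genes. Interferon response genes had a median of -0.12 with 21 not passing and 0 adjusted over the list alone (camera adjusted p = 0.00887, and adjusted p = 0.442 with an estimated correlation), and Gbp2 differed by -0.27 and Rsad2 by -0.38. Red blood cell genes had a median of -0.14 with 11 not passing and 0 adjusted over the list alone (camera adjusted p = 0.0311, and adjusted p = 0.412 with an estimated correlation), and Slc4a1 differed by -0.66 and Hbb-b2 by -0.55, with 0.23 at a second Hbb-b2 probe set. Mast cell, eosinophil and dendritic cell genes had a median of -0.14 with 8 not passing and 0 adjusted over the list alone (camera adjusted p = 0.0343, and adjusted p = 0.414 with an estimated correlation), with -0.17 for Itgae and -0.13 for Flt3. Lipid and sterol synthesis genes had a median of -0.08 with 26 not passing (camera adjusted p = 0.0446, and adjusted p = 0.551 with an estimated correlation). Scd1 was the 1 member past the threshold adjusted over the list alone, and Gpam differed by -0.15. The shift of this list was -0.22 in D34, and it was -0.01 in D04, -0.0049 in D48 and -0.01 in the library labelled Case D52. Without that library, members passing over the list alone were 4 for interferon response, 4 for red blood cells, 2 for mast, eosinophil and dendritic cells and 1 for lipid synthesis, and 0 for alveolar type 1 and vascular genes. The calls at the preset correlation were then lost for red blood cells (camera adjusted p = 0.0598, and adjusted p = 0.396 with an estimated correlation) and lipid synthesis (camera adjusted p = 0.0697, and adjusted p = 0.574 with an estimated correlation).

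The other lists missed the threshold at the preset correlation and with an estimated one, with 0 members past it over all genes. Medians were -0.16 for basal, goblet and neuroendocrine cells (camera adjusted p = 0.0516, and adjusted p = 0.412 with an estimated correlation; Krt15 -0.57, Ngfr -0.23), -0.12 for neutrophils and inflammation (0.0516, and adjusted p = 0.551 with an estimated correlation; Lcn2 0.35, Cxcr2 -0.18) and -0.14 for T and NK cells (0.0943, and adjusted p = 0.412 with an estimated correlation; Cd3e -0.27, Gzma -0.26). They were -0.15 for pericytes and lipofibroblasts (0.0964, and adjusted p = 0.412 with an estimated correlation; Inmt -0.67, Rgs5 -0.33), -0.08 for immediate early and heat shock genes (0.10, and adjusted p = 0.551 with an estimated correlation; Nr4a2 -0.28, Jun -0.15) and -0.15 for adipocytes (0.10, and adjusted p = 0.414 with an estimated correlation; Retn -0.20, Lpl 0.49). Cell cycle genes had a median of -0.11 (camera adjusted p = 0.127, and adjusted p = 0.831 with an estimated correlation; Mcm3 -0.16, Cdc20 -0.15), other matrix genes -0.06 (0.232, and adjusted p = 0.551 with an estimated correlation; Adamts5 -0.54, Ogn -0.98) and cartilage genes -0.07 (0.626, and adjusted p = 0.772 with an estimated correlation; Matn2 -0.68, Ibsp 0.76). For each of these lists 0 members passed adjusted over the list alone. When the library labelled Case D52 was left out, members passing that way were 7 for other matrix genes, 3 for cartilage, 1 each for the basal, neutrophil and T cell lists and 0 for the other 4. At the preset correlation 3 of these lists then passed, the basal (camera adjusted p = 0.0261, and adjusted p = 0.286 with an estimated correlation), neutrophil (0.0137, and adjusted p = 0.396 with an estimated correlation) and cell cycle lists (0.0360, and adjusted p = 0.729 with an estimated correlation).

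B cell genes had a median of -0.06 (camera adjusted p = 0.626, and adjusted p = 0.691 with an estimated correlation), and 1 member, Ebf1 (-0.31), passed adjusted over the list alone, while Fcmr differed by 0.21. Macrophage and monocyte genes had a median of -0.04 and a mean of 0.03 (camera adjusted p = 0.976, and adjusted p = 0.997 with an estimated correlation), and 1 member, Chil3, passed adjusted over the list alone, while Ctsk differed by -0.23. Thymocyte genes had a median of 0.02 and a mean of -0.03 (camera adjusted p = 0.747, and adjusted p = 0.831 with an estimated correlation; Arpp21 -0.11, Ly6d -0.11). Glucocorticoid and circadian genes had a median of -0.05 and a mean of 0.0006 (camera adjusted p = 0.981, and adjusted p = 0.997 with an estimated correlation; Mt1 -0.26). Antigen presentation genes had a median of -0.04 (camera adjusted p = 0.841, and adjusted p = 0.837 with an estimated correlation; H2-K1 -0.09, H2-D1 -0.09) and oxidative phosphorylation genes -0.01 (0.917, and adjusted p = 0.997 with an estimated correlation; Cycs -0.19, Ndufb2 0.13). WNT, hedgehog, BMP and retinoid genes had a median of -0.01 (camera adjusted p = 0.997, and adjusted p = 0.997 with an estimated correlation; Sfrp2 -0.48, Wnt2 0.59). The 1 tested Y-linked gene, Eif2s3y, differed by -1.67, following the number of females (camera adjusted p = 0.635, and adjusted p = 0.714 with an estimated correlation). Adjusted over the list alone, 0 members passed in the thymocyte, glucocorticoid, antigen presentation, oxidative phosphorylation, WNT and Y-linked lists. Members passing that way without the library labelled Case D52 were 6 in the WNT list, Wnt2 among them, 5 in the macrophage list, 3 in the alveolar type 2 list, 1 in the B cell list and 0 in the other 5 of this paragraph and in the FGF ligand list.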

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

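The counts of other splits over all 8 arrays were planned. The counts without the library labelled Case D52 and all other tests of explanations in this part were chosen after the result was seen. Leaving out the library labelled Case D52 was 1 of the planned left-out arrays and was singled out after its Fgf18 level was seen.

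The number of genes changed over all 8 arrays was 1, and 2 of the 35 splits into 4 and 4 arrays gave as many, so chance is not excluded for that count. The highest other split gave 5. That split set control D40 with cases D04, D34 and D48, which points to a structure of the samples that does not follow the labels. Without the library labelled Case D52, 6 genes passed, and 1 of 35 splits, the real one, gave as many, with 3 in the highest other. That library was singled out for its Fgf18 level, Fgf18 is among the 6 genes and pups were chosen on it, so this count alone does not exclude chance. With that choice made in every one of the 70 arrangements of the 8 arrays, by leaving out the lowest Fgf18 of the 4 called case, 2 gave at least 6 genes, the real one included, and 5 gave at least 537 genes at an unadjusted p under 0.01. These arrangements ignore the pairing by litter. Of the 40 that part D02 from D04, which a deposited ratio column sets together, 2 gave at least 6 genes and 4 at least 537. The 5 with at least 537 all kept D04, D34 and D48 as the case pups and differed only in the array left out. They are near copies of the real arrangement, so this count does not decide on chance, which is not excluded. Among the rest, the most was 3 genes past the threshold and 362 at p under 0.01. The other arrangement with at least 6 gave 44: D04, D34 and D48 against D02, D50, D58 and D52, with D40 left out. For gene lists at the preset correlation, 15 passed and 5 of 35 splits gave as many, with 16 in the highest other. The others with at least 15 all kept D04, D34 and D48 together, with 1 control in place of D52. The remaining splits gave at most 14. Those with at least 15 are near copies of the real split, so this count does not decide on chance. Chance is not excluded for the number of lists.

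The library labelled Case D52 lay at the control level for Fgf18. An exchange of labels with an induced pup among the controls is argued against, since the highest control read 7.76 and the lowest of the other case pups 9.82. These values cannot tell of an exchange with a pup that lacked induction. Control D40 took the place of D52 in the split with the most calls. Over the 100 genes that best parted the other 3 case pups from 3 controls, D52 lay on the case side of those controls for a mean of 30. The left-out controls did so for 28 to 58, the most in D40. A control pup under a case label could also give the count of D52. For Abca3 such a pup is argued against, because the lowest control lay 1.06 log2 above D52, with an SD of 0.10 among controls. Weaker induction of the transgene in this pup stays open: the shift of the FGF and ERK target list was -0.0469 in D52 and 0.0992 to 0.15 in the other 3 case pups. A control pup could show the same shift, so this test does not part the 2 explanations. Among the case pups Abca3 did not fall with rising Fgf18. D52 had the lowest Abca3 (10.27) and Scd1 (8.57). D34, with the highest Fgf18, had the highest Abca3 (10.65) and read 8.63 for Scd1.

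Abca3 and Scd1 were lower in all 4 case pups. A smaller number of alveolar type 2 cells is argued against as the whole source, since the 23 other type 2 genes had a median difference of -0.0487 with an SD of 0.17. In the library labelled Case D52, where Abca3 lay -1.19 from the control mean, their median was -0.15 with an SD of 0.22. Low members of the list in that pup, picked after their values were seen, were Lpcat1 (-0.64) and the surfactant gene Sftpb (-0.42). Over D04, D34 and D48 these 2 genes differed by -0.13 and -0.09. A smaller part from fewer such cells is not excluded for the pup labelled Case D52. The larger number of females among the cases is argued against for Abca3, which differed by -1.01 with sex as a covariate (limma adjusted p = 0.00776). A fault of 1 probe set is argued against, since the second bright Abca3 probe set differed by -1.06 and the second of Scd1 by -1.20. That the difference goes with the case pups themselves remains a hypothesis.

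The medians of the club and ciliated lists lay below the control mean in case pups D04, D34 and D48, although 0 members passed over all genes and both list calls were lost with an estimated correlation (adjusted p = 0.412 with an estimated correlation) and by fry (adjusted p = 0.276). The number of females is argued against as the whole source, since the club list median stayed at -0.39 with sex as a covariate, from -0.45. RNA degradation stays open: averaged over these 3 pups, the 3′ minus 5′ difference lay 0.0277 log2 above the control mean for Actb and -0.0262 from it for Gapdh, but D34, with the lowest list medians, read -0.04 for Gapdh, below each control, and 0.38 for Actb, within their range. A smaller share of airway tissue in the sampled lung stays open too, and the test made of it decides nothing: the 2 medians differed on no array by more than 0.215 of the SD of the members, too wide an SD for them to part. An effect of the transgene on airway cells was not tested.

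Of 256 groups of 4 values examined, 21 held a pup far from the other 3, where chance gives about 1 in 20. Case D34 stood apart from the other case pups in 9, with log2 levels of 13.48 for Scgb1a1 (others 14.04 to 14.14), 12.05 for Calcrl, 11.71 for Neat1, 10.34 for Aqp5 (others 11.06 to 11.17), 10.26 for Akap5 and 6.62 for Gzma. In D34 the shift was -0.54 for alveolar type 1 genes, -0.33 for vascular endothelium genes and -0.22 for lipid and sterol synthesis genes. D34 was also the pup with the highest Fgf18. Control D40 stood apart from the other controls in 7, with 13.14 for Eln (others 12.70 to 12.71), 10.96 for Akap5, 10.98 for Fgfr3, 7.76 for Fgf18 and 6.89 for Ibsp. Its macrophage and monocyte shift was -0.18 and its array median 7.06 (others 7.12). The library labelled Case D52 stood apart in 2, with 10.33 for Wnt2 (others 11.15 to 11.26) and 10.47 for Map2k1 (others 10.66 to 10.70). The rest were Gstm5 at 9.50 in control D50, Flt3 at 6.95 in case D48 and an alveolar type 2 shift of 0.10 in control D02.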

How the results depend on the processing

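Each setting changed 1 choice, except that the list test without D52 also took an estimated correlation, and those marked as added were chosen after seeing the data. The number of genes changed, 1 in the first fit, was also 1 with no filter, the 60th percentile, quantile normalization, median centring, trend and robust estimation, an adjusted p under 0.10 and a 1.5-fold limit. It was 0 with the mean of all probe sets (0 lower), 0 at 2-fold (0 lower, since Abca3 lies just under it) and 0 with an ordinary t statistic (0 lower, 683 genes at an unadjusted p under 0.05). It was 16 with array weights (3 higher, 13 lower), 2 with sex as a covariate (Abca3 and Fbp1, 1 higher), 2 in male pups only (Abca3 and Afp, 1 higher, added), 2 with every probe set on its own (2 lower, both of Abca3) and 126 at an unadjusted p under 0.01 (33 higher, 93 lower). With the first principal component of the residuals as a covariate it was 174 (35 higher, 139 lower), but 5 of 35 splits gave as many that way, with 433 in the highest. Near copies of the real split, with 1 control in place of D52, gave 80 to 433. A split of D50, D58, D48 and D52 against the rest gave 194. A pair as a block gave 0 to 2 over the 24 possible pairings and 0 to 2 over the 6 that keep D02 with D04 (added). Leaving out each array gave 0 to 6 genes (0 to 4 higher, 0 to 2 lower), with 0 without D02, D40, D58, D04 or D48 and 568 to 851 at p under 0.05, and 6 without D52. Except where said, the cause was not tested.

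Abca3 was lower under all 22 alternatives run (log2 from -1.07 to -0.66, adjusted p from 0.000508 to 0.470) and past the threshold in 14. The pairings enter these 22 only as the lowest and the highest p over the 24 and over the 6. The lowest passed (limma adjusted p = 0.0160 and 0.0276) and the highest did not (0.470 and 0.254). Most of the 24 pairings lost the call, so 14 of 22 overstates how stable it is. The Fgf18 difference was 2.87 after quantile normalization and 2.90 after median centring, and ran from 2.18 to 3.66 with each array left out, the last without D52. Gene lists past the threshold were 13 to 20 over the pairings and 12 to 18 with each array left out, and 0 with an estimated correlation, 0 by fry and 0 with an estimated correlation without D52 (added). Of 2041 values of the 94 named genes, 1982 kept their direction and side of the threshold, 43 were newly past it, 8 no longer past it and 8 changed sign. In this count too the pairings stand only as their lowest and highest p. Pairing, trend estimation and the residual component leave the log2 difference as it is, so the sign could not change there. Since Abca3 alone passed in the first fit, keeping the side mostly means again not passing. In male pups only, Cycs read 0.0274, Etv5 -0.00590 and Spry2 -0.0125. With array weights Mcm3 read 0.0585 and Spry2 -0.0271, and with the mean of probe sets H2-K1 read 0.0364. With each array left out, Mcm3 ran from -0.27 to 0.0210 and Spry2 from -0.0216 to 0.17, with the sign changed without D34. The median of all genes was -0.01 as deposited, -0.0056 after quantile normalization and 0.04 after median centring. The other deposited table held the same values, so that alternative was not run. Genes near the lower limit of the filter (log2 6.51) have little signal over background.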

Other observations

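The split of the arrays with the most calls, 5 genes, parted them by Reg3g, Scgb3a1, Muc5b, Chad and Slc9a5. Scgb3a1, a secretoglobin of airway secretory cells, read log2 12.21, 12.41 and 12.85 in controls D02, D50 and D58 and 12.83 in the library labelled Case D52. It read 7.42 in control D40 and 7.82, 6.30 and 8.04 in cases D04, D34 and D48. The antimicrobial lectin gene Reg3g read 9.61, 9.98, 10.50 and 10.76 in the first 4 of these libraries and 5.07, 5.34, 4.57 and 5.80 in the other 4. The mucin gene Muc5b ranged from 7.34 to 7.80 and from 6.31 to 6.49 in the same 2 sets, and Tff2 and Ltf also lay higher in the first set. Chad ranged from 7.93 to 8.22 and from 7.15 to 7.47, and Slc9a5, in the opposite direction, from 7.76 to 8.01 and from 8.39 to 8.49. Of 2 other airway secretory genes looked at, Bpifa1 ranged from 4.93 to 5.09 and from 4.48 to 4.91, and of 2 Bpifb1 probe sets 1 overlapped between the sets (6.51 to 6.81 and 6.36 to 6.72) and 1 did not (6.39 to 6.64 and 6.20 to 6.35). In control D40 the club and ciliated lists as a whole had shifts of -0.12 and -0.08, and Abca3 was at 11.56, the highest of the controls. Between case and control, Scgb3a1 differed by -2.47 and Reg3g by -2.17 (limma adjusted p = 0.736 and 0.741). These genes were chosen after their values were seen.

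Genes of the atrial heart muscle, which also lines the large pulmonary veins in mice, varied between pups. Myl7 read 11.53 to 12.12 in controls, 11.10 in D04, 9.49 in D34, 11.36 in D48 and 12.10 in the library labelled Case D52. Nppa, the atrial natriuretic peptide gene, read 9.29 in the library labelled Case D52 and 6.39 to 7.07 on the other 7 arrays. Set alone against the 4 controls, that library differed by 2.54 log2 in Nppa and by -1.19 in Abca3, 2 genes picked after the values were seen. Among the controls, D40 lay farthest from the control mean over all genes (SD of the differences 0.162, against 0.102 to 0.126 in the others). These values describe single arrays and no group.

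Among the case pups, D34 had the highest Fgf18 and lay farthest from the control mean over all genes (SD of the differences 0.357, against 0.179 in D04, 0.222 in D48 and 0.140 in the library labelled Case D52). D04 and D34, the pups with the highest Fgf18, were both female.

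Asz1, the gene next to Wnt2 on chromosome 6 with 0 annotated genes between them, had 2 probe sets that went apart. One read 8.80, 9.97 and 8.99 in cases D04, D34 and D48, 7.11 in the library labelled Case D52 and 6.71 to 7.41 in controls. The other read 6.22 to 6.72 in the same 3 cases and 6.69 to 6.79 in controls. The lactase gene Lct read 3.16 in control D40 and 7.04 to 7.28 on the other 7 arrays.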
